A study of Oryza sativa with 18 samples.

How the data were processed

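Messenger RNA of rice leaves was measured by RNA sequencing in 18 libraries. They came from 3 genotypes, the wild-type cultivar Ningjing 4 and knockout lines of the FK506-binding proteins FKBP57 and FKBP73, kept in normal nutrient solution or exposed to 150 mM NaCl for 4 hours. The sample labels give no time for the control libraries. A difference in harvest time or handling could therefore not be told apart from salt in the salt comparisons. Each of the 6 groups had 3 biological replicates per the series design. Per the labels' protocols, mRNA was selected with poly-T beads, copied from random primers and sequenced on an Illumina NovaSeq. The protocol names no step that marks the strand, and the strand setting of the counting is not given in the sources used here. Reads of overlapping or antisense genes may therefore not have been told apart. Apart from the strand, reads of near-identical copies may not have been told apart either.

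The values are whole-number counts of reads per gene, as deposited by the authors, in 1 table of 37863 genes with RAP-DB identifiers. The submitters' processing notes name fastp 0.22.0, HTSeq 0.9.1 and the genome build IRGSP-1.0. The aligner, the annotation release and any filter are not given in the sources used here. Library totals ran from 27601098 to 39894394 counts, and 5242 genes had no count in any library.

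The counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 25957 genes holding 99.97% of all counts. Libraries were scaled by TMM, with factors from 0.779 to 1.11. Library size alone, without these factors, would shift the median of all genes by 0.129 for salt in the FKBP57 knockout, by -0.123 for that knockout against wild type and by -0.127 against the FKBP73 knockout under control, and by 0.16 for the difference of its salt response. Fold changes are relative to the TMM scale, and RLE moved no median by over 0.019. A quasi-likelihood model with 6 group means was fitted to all 18 libraries, leaving 12 residual degrees of freedom, and 11 contrasts were tested. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The common dispersion was 0.142, a biological coefficient of variation of 37.7%. CPM values below are computed from the counts with the TMM-scaled totals, and log2-CPM values carry a prior count of 2. Standard errors of log2 fold changes were derived from the F statistics.

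Neither the count table nor the reference table used here (assembly ASM3414082v1) pairs these identifiers with gene names: 1 identifier was found in it. Genes are therefore printed as identifiers, at most 2 higher and 2 lower per comparison, and the FKBP57 and FKBP73 genes themselves were not analysed here, so the knockouts were not checked at their targets. The rule for printed genes was fixed before the data were examined. It took the largest changes among called genes with a mean of at least 10 CPM in the higher group and no overlap between the libraries of both groups, plus members of the fixed lists. Its further condition of an informative name selects no gene, so it was dropped after the identifiers were seen. The rule as fixed also allowed more genes per comparison, and the limit of 2 higher and 2 lower was not part of it. List members are printed only where they are among these identifiers.

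Gene lists were defined by identifier from prior knowledge of rice genes, not from a table used here, so a wrong membership cannot be excluded. Before the data were examined, 14 lists with 129 identifiers were fixed, of which 126 identifiers were tested. The lists of photosynthesis and heat shock (15 identifiers, 13 tested) were added after some rows of the table and the library totals had been seen. Another 18 lists defined by product names were not run. Lists with at least 3 tested genes were compared with all other genes by camera in limma 3.58.1, with a preset inter-gene correlation of 0.01 and adjustment over the 15 lists within a comparison. Where a list median is printed, genes without counts in a compared group were set to the floor of 3 counts over that group. The root marker list kept 2 tested genes and had no set test.

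The alternatives fixed before the data were examined were DESeq2 1.42.0 with its own size factors, RLE in place of TMM, no filter on low counts, a mean of at least 5 CPM, a fit of only the groups compared, the replicate number as a block, and each replicate left out in turn. For lists they were an estimated correlation and fry. A fit without 3 libraries, picked by eye from the principal components, was chosen after seeing the data, as was an estimated correlation in the fits that left out libraries. Correlations between knockout effects were set beside sham groups drawn from the pooled covariance of the libraries within groups (100 draws). Earlier schemes that dealt or resampled the deviations themselves were dropped, since the deviations of 3 replicates sum to 0 and sham groups could cancel.

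The procedure was tested on simulated data in which 66, 67 and 67 genes were changed by 1, 1.5 and 2 on the log2 scale. Changed genes were taken from those with a mean of at least 1 CPM. Counts were drawn gene by gene from negative binomials with edgeR's dispersions, so variation shared between genes was not simulated. The rates below describe such data and may not hold for the real libraries. For salt in wild type (25666 genes), edgeR recovered 64.2% of genes changed by 2, 53.7% at 1.5 and 15.2% at 1, and 4.3% of its calls were unchanged genes. For the FKBP57 knockout against wild type under control (25659 genes) it recovered 73.1%, 58.2% and 25.8%. For the difference of the salt responses (25656 genes) it recovered 31.3%, 13.4% and 1.52%. In the simulated salt comparison in wild type (25957 genes), DESeq2 made 182 calls, of which 57 were unchanged genes. Intervals, floors and folds over a floor of 3 counts per group cover counting error only.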

Results

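Leaf mRNA was counted in 18 rice libraries, 3 for each of wild type, the FKBP57 knockout and the FKBP73 knockout under control and salt conditions. FKBP57 and FKBP73 belong to the FK506-binding proteins, a family of peptidyl-prolyl isomerases. The series title links both proteins to salt tolerance through the SOS pathway, which exports sodium. Total counts were 28904403 to 39894394 in the wild-type control libraries and 35440909 to 37320965 in the wild-type salt libraries. They were 27601098 to 31430919 under control and 31253988 to 34630598 under salt in the FKBP57 knockout, and 29122778 to 31854526 and 28344668 to 33443482 in the FKBP73 knockout.

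The first principal component of log2-CPM held 44.4% of the variance and the second 21.3%. Salt libraries scored from -18.3 to 129 on the first component and control libraries from -129.3 to 15.5. Wild type control 3 was at 2.4 on the first component, above FKBP57 knockout salt 3, against -115.1 and -123.6 for wild type control 1 and 2. On the second component it was at -99.8, against 32.1 and 12.9. The FKBP57 knockout controls 1, 2 and 3 were spread over -58.4, 71.2 and -154.3, and control 2 correlated with the others at 0.918 and 0.844. FKBP57 knockout salt 3, at -18.3 on the first, had the lowest score of the salt libraries. An alternative fit left out wild type control 3, FKBP57 knockout control 3 and FKBP57 knockout salt 3, which were chosen by eye after seeing the data. It kept FKBP57 knockout control 2, which lay about as far from control 1 as control 3 did. Within groups, the correlation of log2-CPM between replicates ran from 0.844 to 0.98, and the chi-square per degree of freedom was at least 25, so no pair was a repeated library.

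**Figure D1:**
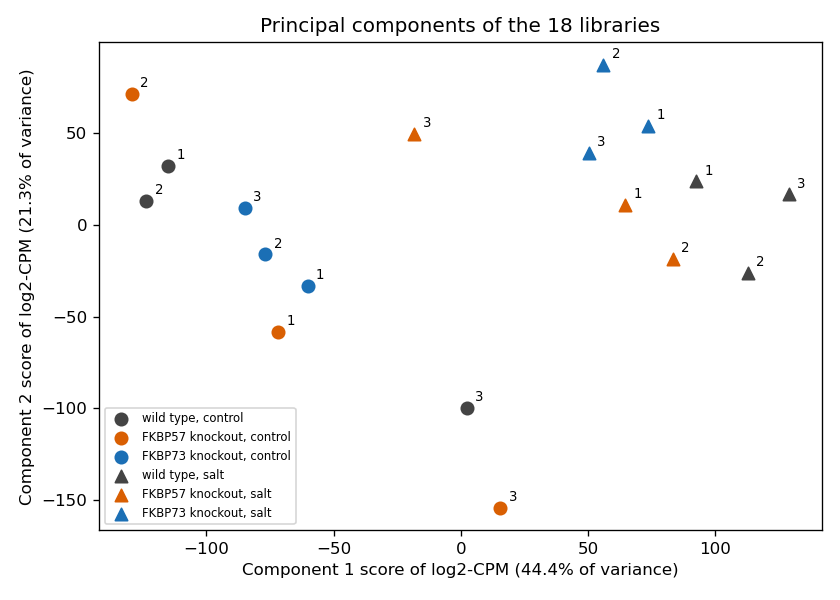
Principal component scores of log2-CPM for the 18 libraries (horizontal, component 1 with 44.4% of the variance, vertical, component 2 with 21.3%). Circles are control and triangles salt libraries, colours are genotypes and digits are replicate numbers, and wild type control 3 and FKBP57 knockout control 3 lie lowest at -99.8 and -154.3.

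Salt raised genes of abscisic acid signalling and of the LEA proteins and dehydrins in wild type. Abscisic acid is the hormone of water deficit, and LEA proteins accumulate in drying tissue. All 9 tested genes of the LEA list rose, with a median log2 fold change of 4.8 (2.87 to 9.27 over genes), and 18 of 24 abscisic acid signalling genes rose, with a mean of 1.97 (SD 1.6). Of the stress transcription factors, 8 of 13 rose and 1 fell, and of the abscisic acid synthesis and breakdown genes 5 of 9 rose and 2 fell. Of the 18 genes of the SOS pathway and sodium and potassium transport, 7 rose, none fell and 11 did not pass the test. The 3 secondary wall marker genes, the cellulose synthases of vascular and fibre walls, all fell, by 1.02 to 1.43 on the log2 scale.

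In wild type, edgeR's quasi-likelihood test called 6364 of 25957 genes at the adjusted threshold, 3539 higher and 2825 lower, of which 4518 changed at least 2-fold. Os03g0830500 had 17.8 ± 12.8 CPM (SD, n = 3) under salt and no count in the controls, at least 632-fold higher, and Os01g0348800 had 13.8 ± 7.33 CPM and no count, at least 491-fold higher. Os11g0522900 was lower by a log2 fold change of -9.24 (SE 2.02, edgeR adjusted p = 0.005) and Os08g0101100 by -8.88 (SE 1.88, edgeR adjusted p = 0.0041). By camera, the LEA list (adjusted p = 1.5e-07), abscisic acid signalling (2.5e-12) and stress transcription factors (0.00096) rose against other genes. So did the SOS and transport list (0.0074) and the list of abscisic acid synthesis and breakdown (0.024). With an estimated correlation none of these lists passed, at adjusted p = 0.13, 0.092, 0.2, 0.24 and 0.2 in that order. Heat shock (0.0016), jasmonate (0.023) and antioxidant genes (0.036) were called up and the secondary wall markers down (0.013), and with an estimated correlation these had adjusted p = 0.13, 0.16, 0.13 and 0.2. Adjusted over the list alone, 9 LEA genes, 19 abscisic acid signalling genes and 7 SOS and transport genes rose. The count was 4237 without control 1, 3604 without control 2 and 3093 without salt 3. Of the calls, 2883 were higher and 1493 lower without salt 2, and 2073 higher and 1020 lower without salt 3. The antioxidant call ended without control 3 or salt 2, at adjusted p = 0.086 and 0.062. Without the 3 libraries chosen by eye, the antioxidant and wall calls both had adjusted p = 0.087.

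In the FKBP57 knockout 8 of 9 LEA genes rose, with a median log2 fold change of 5.56 (2.97 to 8.18, with 1 gene without counts in the controls set to the floor of 3 counts over the group), and of the abscisic acid signalling genes 13 of 24 rose, with a mean of 1.82 (SD 1.65). Of the heat shock genes 3 of 6 rose, and of the stress transcription factors 8 of 13 rose and 1 fell. Of the SOS and transport genes 4 of 18 rose and none fell. None of the 3 secondary wall markers passed the test, with log2 fold changes from -0.19 to 0.06.

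edgeR called 1641 genes for salt in the FKBP57 knockout, 1204 higher and 437 lower, with 1217 changed at least 2-fold. Os04g0415800 had 24.5 ± 7.97 CPM (SD, n = 3) under salt and no count in the controls, at least 689-fold higher, and Os05g0381400 rose by 8.68 (SE 0.93, edgeR adjusted p = 0.00012) on the log2 scale. Os04g0518400 changed by -4.11 (SE 0.69, edgeR adjusted p = 0.0024) and Os04g0644400 by -3.8 (SE 0.93, edgeR adjusted p = 0.023). Abscisic acid signalling, the LEA list and heat shock were called up by camera (adjusted p = 1.4e-18, 1.2e-13 and 3.7e-05), and these 3 calls held with an estimated correlation in the fit of all libraries (adjusted p = 0.022, 0.038 and 0.04). Without FKBP57 knockout control 2, control 3 or the 3 libraries chosen by eye, 0 lists were called with an estimated correlation in any comparison. Stress transcription factors (3.5e-05), SOS and transport (0.0046) and abscisic acid synthesis and breakdown (0.005) did not hold with it, at adjusted p = 0.15, 0.21 and 0.14. Adjusted over the list alone, 9 LEA genes, 16 abscisic acid signalling genes and 8 SOS and transport genes rose. The SOS and transport call and the call of abscisic acid synthesis and breakdown ended without control 2, at adjusted p = 0.081 and 0.061. The count of genes was 914 without control 1, 2974 without control 2, 745 without salt 1 and 848 without salt 2. It was 141 in a fit of only these 6 libraries (133 higher and 8 lower) and 4695 without the 3 libraries chosen by eye. The balance of higher and lower calls moved with the fit. It was 743 to 171, 1559 to 1415 and 1307 to 721 without control 1, 2 and 3, and 643 to 102, 706 to 142 and 1231 to 377 without salt 1, 2 and 3. It was 2337 to 2358 without the 3 libraries, 1032 to 426 under the stricter filter and 1760 to 1172 by DESeq2. Jasmonate genes were called up without control 1 (0.02) or salt 1 (0.045), and photosynthesis genes down without control 2 (0.00054). These had adjusted p = 0.12, 0.18 and 0.25 with an estimated correlation in the same fits.

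In the FKBP73 knockout 8 of 9 LEA genes rose, with a median log2 fold change of 3.92 (2.67 to 8.24), and 15 of 24 abscisic acid signalling genes rose, with a mean of 1.94 (SD 1.58). Of the SOS and transport genes 7 of 18 rose, 1 fell and 10 did not pass. Of the jasmonate genes 3 of 4 rose. Of the secondary wall markers 2 of 3 fell, and the list's values ran from -1.27 to -0.83. Of the 7 photosynthesis genes 1 fell, and the mean of the list was -1.57 (SD 0.5).

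For salt in the FKBP73 knockout edgeR called 3722 genes, 2304 higher and 1418 lower, with 2658 changed at least 2-fold. Os03g0645900, a member of the abscisic acid synthesis and breakdown list, rose by 8.39 (SE 1.03, edgeR adjusted p = 0.00013) on the log2 scale. Os04g0415800 rose by 8.35 (SE 0.71, edgeR adjusted p = 2.3e-05). Os05g0503650 changed by -6.31 (SE 1.51, edgeR adjusted p = 0.012) and Os02g0308400 by -5.83 (SE 1.5, edgeR adjusted p = 0.017). Camera called abscisic acid signalling (8e-15), the LEA list (3.6e-09), jasmonate (0.0044), heat shock (0.0082) and stress transcription factors (0.0082) up. It also called SOS and transport (0.015), abscisic acid synthesis and breakdown (0.021) and osmolyte metabolism (0.021) up. With an estimated correlation all of these, in that order, had adjusted p = 0.05, 0.084, 0.084, 0.18, 0.29, 0.29, 0.18 and 0.18, and none was under the threshold. Photosynthesis (0.0082) and the secondary wall markers (0.015) were called down, with adjusted p = 0.3 and 0.22 with an estimated correlation. Adjusted over the list alone, 9 LEA genes, 20 abscisic acid signalling genes and 9 SOS and transport genes rose and 1 of the last list fell. The osmolyte call ended without control 1, at adjusted p = 0.056. The count of genes was 2203 without control 1, 2196 without control 3, 1908 without salt 1 (1373 higher and 535 lower) and 1967 without salt 2 (1431 higher and 536 lower). It was 7150 in a fit of only these 6 libraries (3617 higher and 3533 lower) and 5615 without the 3 libraries chosen by eye.

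**Figure D2:**
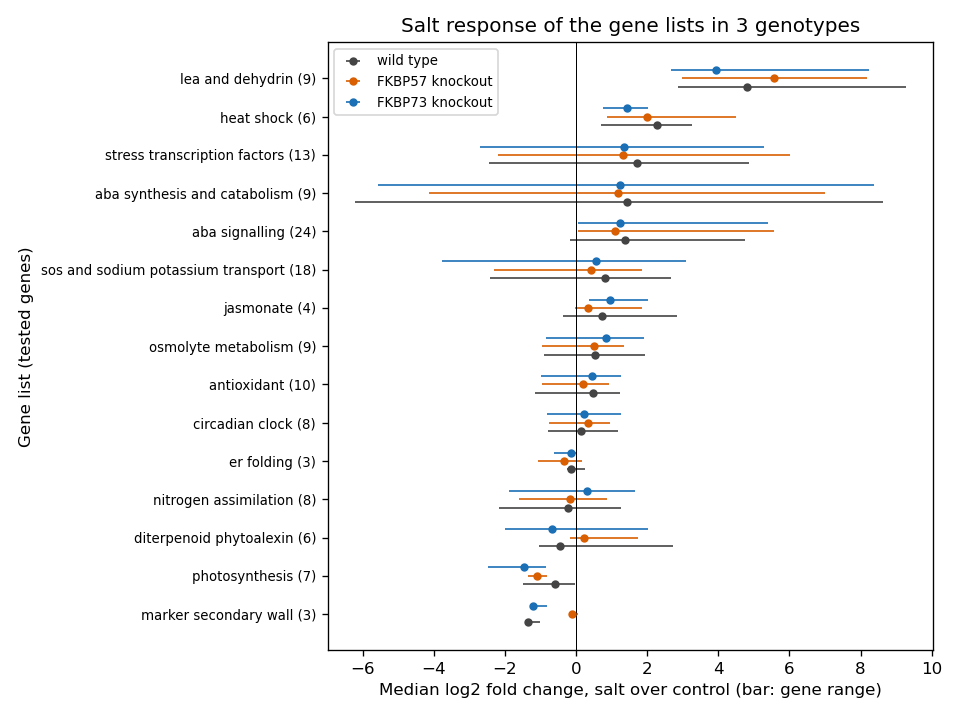
Median log2 fold change of salt over control (horizontal) for each gene list with at least 3 tested genes (vertical, number of tested genes in parentheses) in the 3 genotypes, with genes without counts in a group set to the floor of 3 counts over it. Bars run from the lowest to the highest gene of a list, and the LEA list has medians of 4.8 in wild type, 5.56 in the FKBP57 knockout and 3.92 in the FKBP73 knockout.

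The salt responses of the 3 genotypes shared 1264 genes called in the same direction, 999 higher and 265 lower. Wild type and the FKBP57 knockout shared 1111 genes higher and 320 lower, where independent lists would share 164 and 47.6, and no gene was called in opposite directions. Wild type and the FKBP73 knockout shared 1996 higher and 970 lower, where independent lists would share 314 and 154, and 1 gene was called in opposite directions. Across genes, which are not independent replicates, Pearson's correlation of log2 fold changes was 0.76, 0.77 and 0.77 for the 3 pairs of genotypes. Of the 6364 wild-type calls, 94.9% had the same sign in both knockouts. These comparisons share no libraries.

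Whether the salt response itself differed was tested by its difference between each knockout and wild type. edgeR called 0 genes for the FKBP57 knockout, with 1612 genes at an unadjusted p under 0.05 where 1298 would arise by chance, and DESeq2 called 26. It called 0 for the FKBP73 knockout, with 777 genes at an unadjusted p under 0.05, and DESeq2 called 3. A count below 1298 does not show that the responses were alike. The FKBP57 knockout against wild type under control had 785 such genes although 53 were called. The lower counts of salt calls in the knockouts are therefore not shown to be a different response. On simulated data, the test for the FKBP57 knockout recovered 31.3% of genes whose response differed by 2 on the log2 scale and 1.52% of those that differed by 1. Of the lists, the secondary wall markers were called, with a mean difference of 1.19 (SD 0.12 over 3 genes) for the FKBP57 knockout (camera adjusted p = 0.0022, and adjusted p = 0.53 with an estimated correlation). That call ended without wild type control 3 (0.09) or FKBP57 knockout control 2 (0.14). The SOS and transport list had a median difference of -0.22 (-1.56 to 4.03 over genes, camera adjusted p = 0.38) for the FKBP57 knockout. For the FKBP73 knockout it was -0.19 (-1.51 to 1.77, with 2 genes set to the floor, camera adjusted p = 0.43). Without wild type salt 2 the list was called lower for the FKBP57 knockout (0.048), but not with an estimated correlation (adjusted p = 0.6). Stress transcription factors were called lower for the FKBP73 knockout without wild type control 3 (0.018) or wild type salt 2 (0.043), and with an estimated correlation these had adjusted p = 0.89 and 0.7. Without the 3 libraries chosen by eye, they were also called lower for the FKBP73 knockout (0.013), and jasmonate genes were called lower for the FKBP57 knockout (0.043), with adjusted p = 0.88 and 0.48 with an estimated correlation. Without FKBP57 knockout control 1, edgeR called 1 gene for the FKBP57 knockout, and without the 3 libraries chosen by eye 1 gene for the FKBP73 knockout.

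Under control conditions the FKBP57 knockout differed from wild type in few genes, several of them near presence and absence. Os03g0115800 had 104 ± 6.21 CPM (SD, n = 3) in the knockout and no count in wild type, at least 3690-fold higher. Os03g0299700 had 75.5 ± 23.9 CPM and no count in wild type, at least 2680-fold higher. Os01g0382450 was at 0.0607 ± 0.0625 CPM against 14.1 ± 5.55 in wild type, and Os01g0672600 at 0.168 ± 0.166 against 11.5 ± 5.85. No gene of the fixed lists was called. edgeR called 53 genes, 41 higher and 12 lower, and all 53 changed at least 2-fold. The LEA list was called lower by camera, with a median of -0.77 and 1 gene set to the floor (adjusted p = 0.048), but not with an estimated correlation (adjusted p = 0.9). That call ended without wild type 2 (0.074) or 3 (0.86), without FKBP57 knockout 1 (0.54), 2 (0.11) or 3 (0.096), and without the 3 libraries chosen by eye (0.65). Photosynthesis genes were called higher without FKBP57 knockout 2 (0.0064), but not with an estimated correlation (adjusted p = 0.95). The count of genes was 1 in a fit of only these 6 libraries, 21 under the stricter filter, 32 without the 3 libraries chosen by eye and 105 by DESeq2, and without FKBP57 knockout 3 it was 37 higher and 5 lower.

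Under salt, edgeR called 79 genes between the FKBP57 knockout and wild type, 53 higher and 26 lower, with 78 changed at least 2-fold. Os03g0299700 had 77.1 ± 8.59 CPM (SD, n = 3) in the knockout and no count in wild type, at least 2780-fold higher, and Os03g0115800 had 90.4 ± 9.12 CPM against 0.0266 ± 0.0461. Os01g0672600 was lower by a log2 fold change of -6.76 (SE 0.99, edgeR adjusted p = 0.0048) and Os08g0168000 by -5.59 (SE 0.79, edgeR adjusted p = 0.0041). Of the 53 genes called under control, 45 were called under salt, 37 higher and 8 lower in both, where independent lists would share 0.16, and the 2 comparisons have no library in common. Camera called the secondary wall markers higher, with a mean of 0.88 (adjusted p = 0.006), and jasmonate genes lower, with a mean of -0.54 (0.02). Neither held with an estimated correlation (adjusted p = 0.35 for both), and no gene of either list was called. Adjusted over the list alone, 3 wall genes rose and 1 jasmonate gene fell. The wall call ended without FKBP57 knockout salt 1 (adjusted p = 0.069), and the jasmonate call without wild type salt 1 (0.1) or FKBP57 knockout salt 1 (0.07). Without wild type salt 2, abscisic acid signalling (0.012), the LEA list (0.012) and the SOS and transport list (0.0083) were called lower, but none with an estimated correlation (adjusted p = 0.41 for each). The count of genes was 46, 45 and 46 without wild type salt 1, 2 and 3, 51 without FKBP57 knockout salt 3, 42 higher and 12 lower without FKBP57 knockout salt 2, 32 under the stricter filter (18 higher and 14 lower) and 346 by DESeq2.

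**Figure D3:**
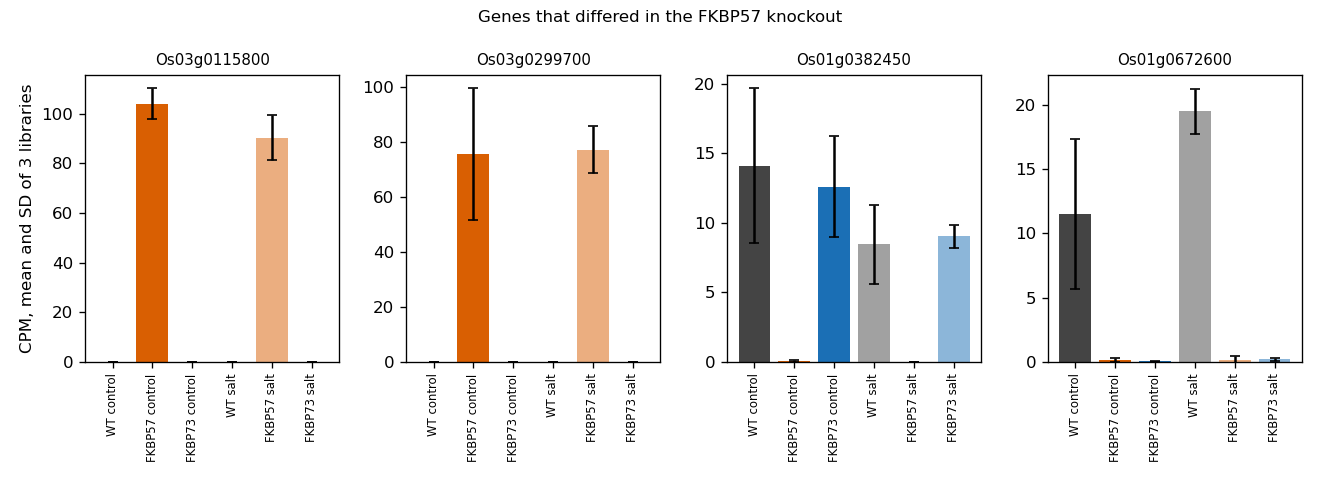
CPM of 4 genes printed for the FKBP57 knockout in the 6 groups, with bars for means and error bars for the SD of 3 libraries. Os03g0115800 and Os03g0299700 reach 104 and 75.5 CPM in the FKBP57 knockout under control and lie near 0 in the other genotypes, while Os01g0672600 is near 0 in both knockouts.

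Between the FKBP73 knockout and wild type, edgeR called 0 genes under control, where DESeq2 called 23, and 0 under salt, where DESeq2 called 61. By edgeR, 739 genes under control and 1330 under salt had an unadjusted p under 0.05, where 1298 would arise by chance. The FKBP57 knockout against wild type under control had 785 such genes although 53 were called. A count below 1298 therefore does not show an absence of effects. Under control the edgeR count of calls was 1 without the 3 libraries chosen by eye. Under salt it was 148 in a fit of only these 6 libraries, 5 without the 3 libraries, 2 without FKBP73 knockout salt 3 and 1 under the stricter filter. No fixed list was called in either condition, and the lowest camera adjusted p were 0.075 for stress transcription factors under control and 0.21 for heat shock under salt. Stress transcription factors were called higher under control without wild type 3 (4e-04), FKBP73 knockout 1 (0.0029) or the 3 libraries chosen by eye (0.00034). These 3 calls had adjusted p = 0.53, 0.66 and 0.34 with an estimated correlation in the same fits. Without FKBP73 knockout control 1, the LEA list was also called higher (0.00072) and phytoalexin synthesis lower (0.0029), but not with an estimated correlation (adjusted p = 0.66 for both). Under salt, heat shock was called lower without wild type 2 (0.025) or FKBP73 knockout 1 (0.03), with adjusted p = 0.62 and 0.61 with an estimated correlation. Without wild type salt 3, abscisic acid signalling (0.013) and osmolyte metabolism (0.042) were called higher and photosynthesis lower (0.045), but none with an estimated correlation (adjusted p = 0.65 for each). Os01g0672600, chosen after its values were seen, was at 0.0433 ± 0.0377 CPM (SD, n = 3) against 11.5 ± 5.85 under control and at 0.184 ± 0.115 against 19.5 ± 1.75 under salt, with edgeR adjusted p = 0.097 and 0.062.

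The overlap of called genes between the knockout effects carries no information for edgeR, because 0 genes were called for the FKBP73 knockout in each condition. At an unadjusted p under 0.05 there were 739 under control and 1330 under salt, where 1298 would arise by chance, which does not show an absence of effects. By DESeq2 the knockouts shared 6 genes under control, out of 105 calls for the FKBP57 and 23 for the FKBP73 knockout. Under salt they shared 30, out of 346 and 61 calls. No chance value was computed for these overlaps, and both comparisons use the same wild-type libraries. Across genes, the correlation of both effects was 0.39 under control, where unchanged groups sharing the wild-type libraries gave 0.41 on average (95% of draws from -0.58 to 0.96), and 0.61 under salt, where they gave 0.46 (-0.21 to 0.89). The covariances were 0.0894 against a simulated 0.175 (-0.161 to 0.759) and 0.248 against 0.0854 (-0.0188 to 0.285). Both observed covariances lay within the simulated range. The 3 wild-type libraries of a condition are too few to split, so part of any excess may come from the shared controls.

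Between the knockouts, edgeR called 48 genes under control, 43 higher and 5 lower in the FKBP57 knockout, and 65 under salt, 52 higher and 13 lower. Os03g0115800 and Os03g0299700 had no count in the FKBP73 knockout and were at least 3200-fold and 2330-fold higher under control, and at least 2900-fold and 2480-fold under salt. Under control Os01g0382450 was lower by a log2 fold change of -7.64 (SE 0.6, edgeR adjusted p = 8e-05) and Os07g0456400 by -1.15 (SE 0.14, edgeR adjusted p = 0.0013). Under salt Os09g0344500 was lower by -4 (SE 0.63, edgeR adjusted p = 0.009) and Os02g0240100 by -2.64 (SE 0.47, edgeR adjusted p = 0.021). Of the 48 genes, 41 were also called under salt in the same direction. Camera called the LEA list lower under control (median -1.59 with 1 gene set to the floor, adjusted p = 0.0045), and under salt jasmonate lower (mean -0.65, adjusted p = 0.00077), abscisic acid signalling lower (-0.24, 0.046), secondary wall markers higher (0.67, 0.017) and photosynthesis higher (0.9, 0.017). With an estimated correlation these had adjusted p = 0.72, 0.081, 0.74, 0.68 and 0.74, and no gene of these lists was called. The jasmonate call held with each of the 6 libraries left out. The LEA call ended without FKBP57 knockout 1 (0.23) and FKBP73 knockout 2 (0.14) or 3 (0.28). The abscisic acid signalling call ended without FKBP57 knockout 1 (0.093) or 3 (0.12), FKBP73 knockout 1 (just over 0.05) or 2 (0.16), or the 3 libraries chosen by eye (0.12). The wall call ended without FKBP57 knockout 1 (0.093) or FKBP73 knockout 1 (just over 0.05), and the photosynthesis call without FKBP57 knockout 2 (0.096) or FKBP73 knockout 2 (0.14). Under control, stress transcription factors were called lower without FKBP57 knockout 3 (0.0046), FKBP73 knockout 1 (0.015) or the 3 libraries chosen by eye (0.0018), with adjusted p = 0.72, 0.7 and 0.52 with an estimated correlation. Without FKBP57 knockout control 2, photosynthesis (0.012) and nitrogen assimilation (just under 0.05) were called higher, with adjusted p = 0.89 and 0.33 with an estimated correlation. The LEA list was called lower under salt without FKBP73 knockout 3 (0.047), but not with an estimated correlation (adjusted p = 0.68).

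The count under control was 27 without FKBP73 knockout 1, 30 without FKBP73 knockout 3, 2 in a fit of only these 6 libraries, 14 under the stricter filter (11 higher and 3 lower) and 115 by DESeq2 (85 higher and 30 lower). Under salt it was 43 without FKBP57 knockout 3, 31 and 38 without FKBP73 knockout 1 and 2, 25 under the stricter filter and 224 by DESeq2 (149 higher and 75 lower).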

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

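The fit without 3 libraries picked by eye was chosen only after the result was seen. The secondary wall markers stood out because their salt response differed between genotypes by the test of the difference itself. The 3 genes had mean log2 fold changes of -1.27 in wild type, -1.1 in the FKBP73 knockout and -0.08 in the FKBP57 knockout. The difference between the FKBP57 knockout and wild type was 1.19 (camera adjusted p = 0.0022). It was not past the threshold with an estimated correlation (adjusted p = 0.53), by fry (0.23), without wild type control 3 (0.09) or without FKBP57 knockout control 2 (0.14). It stood at 0.0087 without the 3 libraries chosen by eye. None of the 3 genes passed the test of the difference over all genes, and all 3 did when adjusted over the list alone.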

How the results depend on the processing

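The fit without the 3 libraries chosen by eye, and an estimated correlation in fits that left out libraries, were chosen after seeing the data, and the other alternatives before the data were examined. The cause of each shift was not tested. RLE in place of TMM and no filter kept each of the 11 counts within 1.5 times its value.

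With DESeq2 the counts were 2932 for salt in the FKBP57 knockout, 105 and 346 for the FKBP57 knockout against wild type under control and salt, 23 and 61 for the FKBP73 knockout, 26 and 3 for the differences of the salt responses, and 115 and 224 between the knockouts. In the simulated salt comparison in wild type, a single data set drawn with edgeR's dispersions, 57 of 182 DESeq2 calls were unchanged genes. DESeq2 was not run on simulated data of the other comparisons, so this share does not carry over to the counts above. The DESeq2 overlap of the knockout effects was 6 genes under control and 30 under salt, and its shared salt response 2035 genes. At an adjusted p under 0.01 the shared response was 486 genes.

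Under the stricter filter, which tests fewer genes, the counts were 21 and 32 for the FKBP57 knockout against wild type, 1 for the FKBP73 knockout under salt, and 14 and 25 between the knockouts. In fits of only the groups compared they were 141 and 7150 for salt in the FKBP57 and FKBP73 knockouts, 1 for the FKBP57 knockout and 2 between the knockouts under control, and 148 for the FKBP73 knockout under salt. Without the 3 libraries they were 4695 and 5615 for salt in the knockouts, 32 for the FKBP57 knockout under control, 1 and 5 for the FKBP73 knockout under control and salt, and 1 for the difference of its salt response.

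With single replicates left out, the counts ran from 3093 to 7525 for salt in wild type, 745 to 2974 in the FKBP57 knockout and 1908 to 3268 in the FKBP73 knockout. They ran from 45 to 54 for the FKBP57 knockout and 0 to 2 for the FKBP73 knockout under salt, 27 to 56 and 31 to 51 between the knockouts under control and salt, and 0 to 1 for the difference of the FKBP57 salt response. Without a replicate, that group had 2 libraries.

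Of 165 list tests 34 were called, and 3 with an estimated correlation. fry called 25 of the 34 in the same direction, and with single replicates left out 31 to 40 were called. For salt, fry also called lists that camera did not. These were antioxidant genes in the FKBP57 (adjusted p = 0.0034) and FKBP73 (0.00097) knockouts, and jasmonate in the FKBP57 knockout (0.0069). Osmolyte metabolism in wild type (0.019), nitrogen assimilation in wild type (0.041) and the FKBP73 knockout (0.0055), and circadian clock genes in wild type (0.043) and the FKBP57 knockout (0.0073) were the others. Where single replicates were left out with an estimated correlation 0 to 5 were called, among them 4 without wild type control 3 or wild type salt 3, and 0 without the 3 libraries. The replicate numbers do not pair the samples: deviations of same-numbered libraries correlated from -0.66 to 0.73, with 14 of 45 pairs over 0.1, and 5 of 18 libraries correlated best with their own number. With the replicate block the counts were 5402, 1391 and 3282 for salt in wild type and the FKBP57 and FKBP73 knockouts, with 37 list calls, and no count of genes moved by over 1.5 times. The list calls it added were stress transcription factors under control, higher in the FKBP73 knockout than in wild type (0.047) and lower in the FKBP57 than in the FKBP73 knockout (0.043), and the LEA list between the knockouts under salt (0.044). These had adjusted p = 0.95, 0.72 and 0.74 with an estimated correlation and no block. Among 363 refits of the printed identifiers, 335 kept their side of the threshold, 28 were no longer past it and none changed sign. With all libraries thinned to the smallest total of 27601098 counts, salt gave 6184, 1607 and 3634 genes in wild type and the FKBP57 and FKBP73 knockouts.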

Other observations

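Neither of the 2 tested root marker genes passed the test in any of the 11 comparisons. Camera did not call circadian clock genes as a list in any comparison (lowest adjusted p = 0.14), and for salt in wild type 2 of 8 rose (camera adjusted p = 0.48). Their log2 fold changes in wild type ran from -0.79 to 1.19. Camera tests a net shift of a list, so opposite changes of its genes can cancel and would be missed. By fry, the circadian clock list was called for salt in wild type (adjusted p = 0.043) and in the FKBP57 knockout (0.0073). The lists of nitrogen assimilation (0.48), diterpenoid phytoalexin synthesis (0.48) and endoplasmic reticulum folding (0.96) were not called by camera for salt in wild type. Of these, fry called nitrogen assimilation (adjusted p = 0.041). Camera placed nitrogen assimilation up, while its mean was -0.09 and its median -0.22.

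Tests of wrong treatment labels, the division of the genotype test and its part on the FKBP73 knockout, tests of a smaller response, of a single segment, of neighbours in other comparisons, and the fit without the 3 libraries chosen by eye were chosen only after the result was seen.

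Fewer genes were called for salt in the FKBP57 knockout (1641) than in wild type (6364). Leaving out 1 library gave at most 2974 genes in the knockout (without control 2) and at least 3093 in wild type (without salt 3). The bound set beforehand, the full wild-type count divided by 1.5, compared unlike fits, so a single library as the cause stays open. Without the 3 libraries chosen by eye the knockout count rose as well, as given above, so libraries that lie apart also stay open as a cause. With all libraries thinned to the smallest total of 27601098 counts the wild-type count was still 3.85 times that of the knockout (6184 against 1607), which argues against depth. A smaller response in the knockout stays open, because the test of the difference called 0 genes and recovered few simulated differences.

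Wild type control 3, FKBP57 knockout control 3 and FKBP57 knockout salt 3 were picked by eye as lying apart, and FKBP57 knockout control 2 lay about as far out as control 3. Over 33 genes of the LEA and abscisic acid signalling lists, the higher of both picked control libraries had a mean log2-CPM of 3.34, below the lowest salt library (4.96, SD 0.34 among salt libraries), and the salt library had 5.33, above the highest control library (3.37, SD 0.45). On genes called between the FKBP57 knockout and wild type in the other condition, both FKBP57 knockout libraries lay at least 2.66 from the nearest library of the other genotypes, and wild type control 3 lay 3.02 from the nearest FKBP57 knockout library, with an SD in their own groups of at most 0.1. These values argue against wrong labels for treatment and against a swap between the FKBP57 knockout and another genotype. A swap of wild type control 3 with the FKBP73 knockout stays open. Over 61 genes called by DESeq2 under salt, wild type control 3 (-1.37) lay on the wild-type side, 0.66 from the nearest FKBP73 knockout control. But wild type control 2 (-0.53) lay among those controls (-0.71 to -0.31), so this score does not separate both genotypes.

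Of the 53 genes called between the FKBP57 knockout and wild type under control, 71.7% also differed from the FKBP73 knockout in the same direction. For these the wild-type libraries alone do not set the difference, and for the rest that stays open. Both comparisons use the same 3 FKBP57 knockout control libraries, which could also raise this share. Without the 3 libraries chosen by eye, 32 genes were called. A hypothesis is that some of the genes lie in small segments that differ in the knockout line. Among the 87 genes called in either condition, 9 pairs were neighbours within 5 tested genes in identifier order, against a median of 1 and a highest of 8 in 10000 random sets (permutation p = 1e-04, the smallest they can give). As many top-ranked genes of 5 other comparisons gave 2 to 5 pairs, above the 95th percentile of 4 for random sets in 2 of them, so random sets understate background clustering, and tandem copies or overlapping gene models may add pairs. A single segment is argued against, since at most 15 of the 87 genes carry identifiers of 1 chromosome.

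The 6 libraries of a comparison make 10 splits, too few for a share under 0.05. For salt, the real split alone (1 of 10) gave as many genes in each genotype, 6364, 1641 and 3722 against at most 0, 601 and 0 in the other splits. For the FKBP57 knockout under salt it was also 1 of 10, 79 against at most 0, and between the knockouts under salt 65 against at most 0. For the FKBP57 knockout under control 2 of 10 splits gave as many, 53 against 9131, and between the knockouts under control 2 of 10, 48 against 413. The split with 9131 genes set wild type control 1 and 2 and FKBP57 knockout control 2 against the other 3 libraries, which points to a structure of the control libraries apart from genotype. So does the split with 413 genes, FKBP57 knockout control 1 and 3 and FKBP73 knockout control 2 against the rest. For the FKBP73 knockout against wild type the real count was 0 in both conditions, so 10 of 10 splits give at least as many by construction, and the others gave at most 0. For the differences of the salt responses 100 of 200 possible relabellings were counted, the real one included. With a real count of 0 all 100 give at least as many by construction, so these splits say nothing about chance. The highest others were 6111 for the FKBP57 knockout, where 14 gave any gene, and 3 for the FKBP73 knockout.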
